A study of Mus musculus with 3 samples.

How the data were processed

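RNA-seq of SB28, a mouse glioblastoma model cell line on the C57BL/6 background, was deposited as 3 libraries of 1 group. Per the labels, libraries were made from 1 µg of total RNA with a TruSeq RNA kit. The labels name no control group, treatment, culture condition, passage or strand setting, and nothing in them says that the replicates came from separate cultures. SDs therefore measure only the spread between these samples, which may be technical, and p-values apply to these samples alone. The series also covers exome sequencing of the line, which is not analysed here.

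The deposited values are raw counts per gene symbol, 1 file per library, with no header. The submitters' processing notes name Bowtie2 2.2.4, HTSeq without a version, and the mouse assembly mm10; they give no role, option or order for them. Each file lists 24421 gene lines and 5 summary lines for reads that were not assigned to a gene. A counter of this kind leaves out reads placed at more than 1 position and reads overlapping more than 1 gene, so genes with near-identical copies can be undercounted. Without a stated strand setting, reads of a gene and of an antisense or overlapping partner cannot be told apart. A spreadsheet had turned 27 symbols into dates, and those lines held 0.228% of the counts. The files hold 0 mitochondrial gene lines.

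Symbols were matched to the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, for gene length, biotype and position. In all, 23350 symbols matched directly, 669 matched through RefSeq synonyms and 402 did not match; the last group held 0.764% of the counts. All 457 distinct genes of the fixed lists had a length. Chi3l1, Nectin2 and Vsir were found under older symbols.

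Counts per 1000000 (CPM) were computed from the deposited counts, over the counts assigned to genes, with the summary lines left out. A gene was called detected at 1 CPM or more in all 3 libraries. For a gene at 0 counts, the limit given is 3 counts, which covers counting error only; PCR copies without molecular identifiers are not independent molecules. The limit was 0.0833, 0.103 and 0.0919 CPM in replicates 1, 2 and 3. Length-scaled CPM used the union exon length.

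The tests and the 32 gene lists of the report were fixed before the data were examined; the tests of explanations in the closing section, with their lists of YAP targets, lipid synthesis genes and genes that escape X inactivation, were added later. With 1 group, no test between groups was possible. For 32 lists, the members detected were counted, and the median of log2(length-scaled CPM + 1) was placed among 10000 random lists of the same size drawn from all genes with at least 1 count. For 18 gene pairs, the log2 ratio of length-scaled CPM was taken within each library with a pseudocount of 0.5 counts, so that a ratio is on the log2(count + 0.5) scale. For 9 pairs of lists, the difference of their medians was taken. A ratio or difference was called larger than the spread between replicates when all 3 libraries lay on one side of 0 and the mean exceeded 2 SD. An exact two-sided sign-flip permutation test was also run. Its smallest p with 3 libraries is 0.25, so no pair can reach the usual threshold.

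Differences between libraries were tested per gene with a chi-square test of the 3 counts with 2 degrees of freedom, after TMM scaling, for genes with a mean count of at least 10, with Benjamini-Hochberg adjustment at 0.05. This test compares libraries with pure counting noise and says nothing about conditions. The common dispersion was estimated with edgeR 4.0.16 and, for comparison, gene-wise with DESeq2 1.42.0, under R 4.3.3. For each list with enough detected members, the median of log2(CPM in a library / mean of the 3 libraries) was taken, and its range over libraries was placed among 10000 random lists matched on mean CPM within 100 ranks. Percentiles among random lists describe these libraries and are not p-values. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

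The steps were tested on simulated data. With counting noise only, the chi-square test called 0% of 12660 genes. With 50 genes changed at each size in 1 library, among 12663 genes, it called 64% at 1.2-fold, 78% at 1.5-fold, 92% at 2-fold and 100% at 3-fold, and 0.0718% of unchanged genes. With a dispersion of 0.04 in 12737 genes, edgeR recovered 0.0399 and the DESeq2 median 0.0263. Of 400 random lists drawn from the real counts, 1.75% reached the top 2.5% of the range of shifts. A share near 2.5% follows from the construction, so this checks the computation only and not lists of related genes.

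Genes are named by a rule fixed before the data were examined. It covers the 4 members of highest mean CPM of every list, and members below detection in every library where fewer than 6 such members exist. It also covers all members of the RAS-MAPK, PDGF, MHC class I, MHC class II, checkpoint and sex chromosome lists, and the genes of the fixed pairs. Further names come from the 20 genes of highest mean CPM, and from the 15 varying genes with the largest ratio between libraries at a mean of at least 10 CPM. Some genes that the rule covers are not reported here. Genes outside the rule are named as chosen after their values were seen. Alternatives covered the detection threshold, scaling, gene length, pseudocounts, the background of random lists, the summary of a list and leaving out each replicate. Averaging replicates 1 and 2 as 1 sample, a background with genes at 0 counts, and DESeq2 size factors and left-out replicates for the list shifts were added after the data were examined.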

Results

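SB28 is a transplantable mouse glioblastoma model line, derived from a brain tumour induced by transposon transfer of oncogenes and used in studies of glioma immunity. The series set RNA-seq beside exome sequencing to describe the line. The comparisons open to its count tables are between genes within the line and between its 3 replicate libraries. Replicates 1, 2 and 3 held 36019009, 28990128 and 32632858 counts assigned to genes, and 15575, 15325 and 15506 genes had at least 1 count. Values below are CPM as mean ± SD over the 3 libraries (n = 3) unless stated otherwise. Replicates 1 and 2 lay close together and replicate 3 apart from both, so most SDs reflect replicate 3, and where 3 values per gene are given they follow the order 1, 2, 3.

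Of 24421 genes, 11379 (46.6%) were detected in all 3 libraries, 12530 lay below 1 CPM in all, 512 were split between libraries and 7788 had 0 counts in all. Among 20499 protein-coding genes, 11083 (54.1%) were detected. The 20 most abundant genes of each library held 8.29% of its counts on average. By mean CPM, the genes were led by the elongation factor Eef1a1 (10092 ± 954), the secreted phosphoprotein osteopontin, Spp1 (6000.0 ± 2073), the actin Actg1 (5625 ± 428) and the intermediate filament vimentin, Vim (5404 ± 100). Thbs1 (4964 ± 427), Flna (4688 ± 567), Pkm (4434 ± 422) and Actb (4113 ± 503) followed, together with Hsp90ab1, Eef2 and Hspa8 between 3781 and 4004 CPM. Sparc, Nedd4, Crabp1, Fn1, Myh9, Itgb1, Scd2 and Lgals1 lay between 2339 and 2856 CPM. The ribosomal RNA precursor Rn45s held 0.441%, 0.496% and 0.397% of the counts of the 3 libraries.

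All 12 genes of the RAS-MAPK pathway were detected, with a median level at the 99.8th percentile of random lists. Nras (162 ± 4.18) was higher than Hras (50.6 ± 9.61). Corrected for length, Nras lay 2.26-fold above Hras (range over libraries 1.89 to 2.502), larger than the spread between replicates. The kinases Braf (49.1 ± 4.18), Map2k1 (86.2 ± 9.59), Map2k2 (121 ± 5.81) and Mapk3 (128 ± 14.7) were present, as were the exchange factor Sos1 (64.9 ± 1.30) and the RAS inhibitors Nf1 (114 ± 13.4) and Rasa1 (275 ± 54.7). All 18 MAPK output genes were detected, at the 100th percentile, led by Ccnd1 (1240.2 ± 22.5), Egr1 (439 ± 5.34), Dusp6 (284 ± 67.4) and Spred1 (284 ± 51.2). Nras lies on chromosome 3 at 103058285 to 103067914 and Hras on chromosome 7 at 141189105 to 141194005 (GRCm38). Counts per gene do not separate a resident gene from an introduced copy of it.

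All 6 PDGF ligands and receptors were detected, at the 95.9th percentile. The ligand Pdgfb (271 ± 22.8), on chromosome 15 at 79995874 to 80014977, lay 6.63-fold above Pdgfa (30.6 ± 1.46) after length correction (range 5.92 to 7.20). Pdgfc reached 105 ± 14.3 and Pdgfd 32.0 ± 5.58. Pdgfrb (120.2 ± 13.3), a receptor prominent in pericytes, lay 4.22-fold above Pdgfra (52.4 ± 8.87), a receptor of oligodendrocyte progenitors (4.002 to 4.54), and 2.31-fold above it without length correction. Both ratios exceeded the spread between replicates. For all 18 gene pairs the exact two-sided permutation p was 0.25, the smallest that 3 libraries allow. The receptor tyrosine kinase list had 11 of 16 members detected, at the 68.5th percentile. Axl (922 ± 78.8), Fgfr1 (368 ± 39.0), Met (305 ± 3.001) and Igf1r (210.4 ± 8.80) led it, while Erbb3, Erbb4, Fgfr3, Kit and Ntrk2 lay below 1 CPM in all libraries.

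Proliferation genes were high in all libraries. All 26 cell cycle genes were detected, at the 100th percentile, led by Ccnd1, Ccnd2 (546 ± 60.8), Top2a (464 ± 114) and Cdk4 (427 ± 22.97). Cdk4 lay 114-fold above Cdk6 (16.1 ± 0.180) after length correction and 26.5-fold without it, and Ccnd1 lay 4.56-fold above Ccnd2 and 2.28-fold without it. Both ratios were larger than the spread between replicates. All 11 cell cycle inhibitors and tumour suppressors were detected, at the 95.7th percentile, with Cdkn2a highest (420, 424 and 242), and with Atrx (253 ± 9.30) and Cdkn1a (160, 164 and 74.4) among the others. Cdkn2a lies on chromosome 4 at 89274471 to 89294653, and its counts do not separate its transcripts for p16 and p19ARF. Of the 20 genes of the p53 list, 19 were detected, at the 99.7th percentile, led by Ccng1 (448 ± 87.4), Zmat3 (139.7 ± 22.96), Cdkn1a and Mdm2 (124 ± 8.24), and Gdf15 lay below 1 CPM. Trp53 itself, chosen after its values were seen, was low at 9.52 ± 0.898 CPM, the 19.9th percentile among detected genes. All 11 mismatch repair and polymerase genes were detected, at the 55.8th percentile (46.4, 47.4 and 69.9 in replicates 1, 2 and 3), led by Msh6 (128 ± 7.69), Pole (80.8 ± 18.9) and Pold1 (59.8 ± 12.5). The methyltransferase gene Mgmt was low at 4.08 ± 0.880.

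Transcripts for MHC class I presentation were mostly present, and those for class II mostly not. Of 22 class I genes, 18 were detected, at the 41.9th percentile. The light chain B2m reached 325 ± 47.1 CPM, against 38.5 ± 11.3 for the heavy chain H2-K1 and 17.7 ± 1.93 for H2-D1. B2m lay 29.5-fold above H2-K1 after length correction, 18.8-fold with the longest transcript and 8.64-fold without correction. H2-K1 lay 1.85-fold above H2-D1 (range 1.44 to 2.16), larger than the spread with all 3 libraries but not without replicate 1. H2-T23 (7.20 ± 0.905), H2-Q4 (3.46 ± 0.397) and H2-M3 (3.27 ± 1.011) were low, and H2-Q6 and H2-Q7 had 0 counts. These heavy chain genes share sequence, and reads placed at more than 1 position were not counted, so their levels are uncertain. The peptide transporter genes Tap1 (2.84 ± 1.37) and Tap2 (4.58 ± 2.14) were low, and the immunoproteasome genes Psmb8 (0.525 ± 0.297) and Psmb9 (0.139 ± 0.125) lay below 1 CPM in all libraries. Psmb10 (14.6 ± 0.818), Psme1 (46.1 ± 11.4), Psme2 (56.0 ± 12.7), Tapbp (89.6 ± 18.8), Tapbpl (5.01 ± 0.940), Erap1 (22.2 ± 2.72) and the class I transactivator Nlrc5 (10.9 ± 1.61) were detected, as were the chaperones Calr (1171 ± 20.7), Canx (772 ± 36.1) and Pdia3 (966 ± 84.1). Of 9 class II genes only H2-DMa (2.22 ± 0.407) was detected at 1 CPM. Cd74 (8 counts in total), H2-DMb1 (8), the transactivator Ciita (2) and H2-Aa (1) lay near 0, and H2-Ab1, H2-Eb1, H2-Oa and H2-Ob had 0 counts. The medians of the lists differed by 3.52 ± 0.15 on the log2 scale, larger than the spread between replicates, and by 6.67 with a pseudocount of 0.1. The class II median itself lay near 0 (0.00925 CPM), so the size of this difference depends on the pseudocount. Of the 16 class I genes that varied between libraries beyond counting noise, 14 were lowest in replicate 3.

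**Figure D1:**
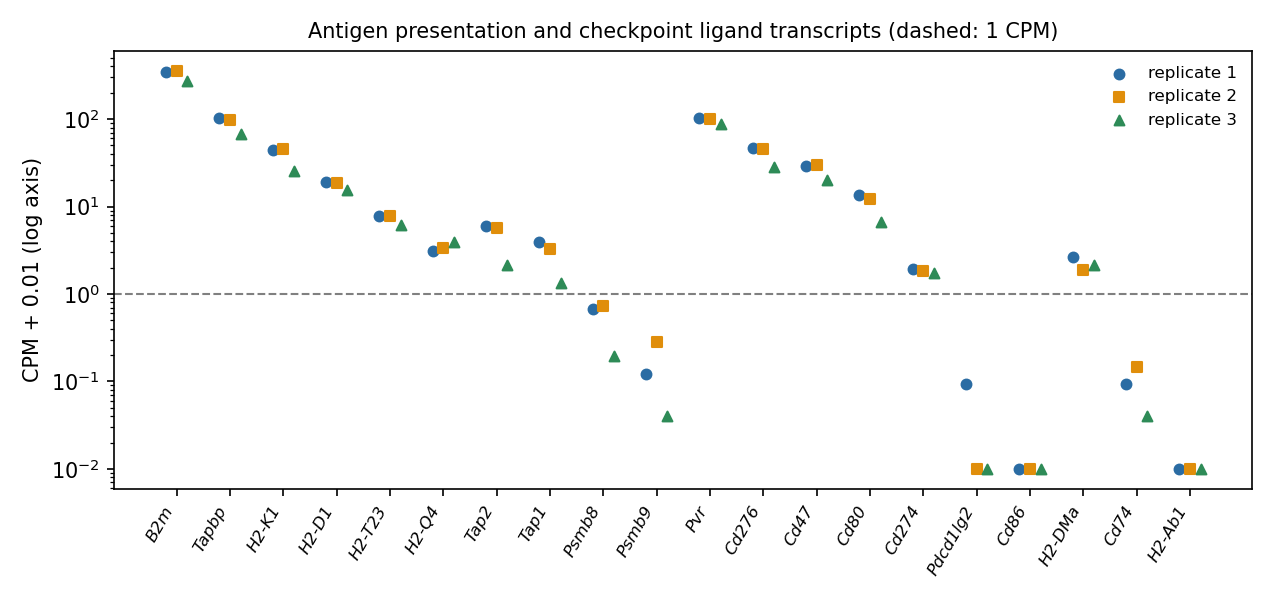
CPM + 0.01 (log axis) of antigen presentation and checkpoint ligand genes in the 3 SB28 libraries, 1 marker per replicate, with a dashed line at 1 CPM. B2m lies near 325 CPM and H2-K1 near 38.5 CPM, while Psmb8, Psmb9, Cd74 and H2-Ab1 lie under the line in every library.

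The list of checkpoint and costimulatory ligands also holds some enzymes and receptors. Of its 22 genes, 9 were detected, 3 were split and 10 lay below 1 CPM in all libraries. The level of the list lay at percentile 1.34 for the mean of the libraries and at 1.81, 1.46 and 0.57 in replicates 1, 2 and 3. Pvr (97.4 ± 8.38), Cd276 (40.4 ± 10.7), Lgals9 (37.7 ± 6.76), the phagocytosis inhibitor Cd47 (26.1 ± 5.38), Nectin2 (14.3 ± 4.47) and Cd80 (10.9 ± 3.76) were highest. The ectonucleotidases Entpd1 (3.33 ± 0.639) and Nt5e (2.82 ± 0.978) were low. Cd274, encoding PD-L1 and lying on chromosome 19 at 29367455 to 29388095, stood at 1.82 ± 0.1001 CPM, and Cd276 lay 21.2-fold above it after length correction (range 16.04 to 24.7), larger than the spread between replicates. Pdcd1lg2, encoding PD-L2, had 3 counts in all, each in replicate 1, against 178 for Cd274. The ratio per base over the pooled libraries was 32.1 (exact 95% interval 10.8 to 157, counting error only), and its size rests on that one library. As a mean over libraries it was 59.5 without replicate 1 and 5.92 with a pseudocount of 5 counts, against 33.7. Tnfsf9, Vsir and Vtcn1 were split. Fgl1 (0.452 ± 0.0278), Ido1 (0.277 ± 0.107), Icosl, Tnfrsf14, Cd40 and Tnfsf4 were under 1 CPM, and Cd86, Cd70 and Fasl had 0 counts. Of the 9 detected genes of the list, 8 varied between libraries and all 8 were lowest in replicate 3.

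The interferon pathway was expressed, and its target genes stood lower. All 11 receptor and signalling genes were detected, at the 92.6th percentile, led by Jak1 (167 ± 5.30), Ifnar1 (105 ± 14.3), Jak2 (49.4 ± 13.5) and Ifngr1 (39.9 ± 4.40). Ifnar1 lay 1.25-fold above Ifngr1 after length correction (1.22 to 1.30) and 2.61-fold without it, both larger than the spread. Of 21 interferon-stimulated genes, 13 were detected, 5 were split and 3 lay below 1 CPM in all libraries (Mx1, Mx2 and Oas1a), with a level at percentile 13.3 for the mean of the libraries and at 20.1, 21.65 and 4.41 in replicates 1, 2 and 3. Ifit2 (57.1 ± 4.28), Ifit1 (31.1 ± 11.4), Bst2 (19.5 ± 6.45) and the RNA sensor Ifih1 (18.4 ± 9.07) were highest. The signalling list exceeded the stimulated genes by 2.81 ± 0.36 on the log2 scale, larger than the spread between replicates. All 13 detected stimulated genes varied between libraries beyond counting noise and all 13 were lowest in replicate 3.

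Secreted factors were led by Spp1, the macrophage growth factor Csf1 (267, 263 and 433), Mif (221 ± 12.95) and the chemokine Cxcl12 (99.8 ± 20.7). Of 30 cytokines and chemokines, 19 were detected and 5 had 0 counts. The level of the list lay at percentile 25.4 for the mean of the libraries and at 46.8, 44.8 and 6.11 in replicates 1, 2 and 3. Csf1 lay 6.27-fold above Il34 (18.6 ± 2.29), the other ligand of its receptor, after length correction and 16.9-fold without it. Tgfb1 (22.3 ± 6.57) lay 7.56-fold above Tgfb2 (3.29 ± 0.511), and 13.1-fold with the longest transcript. Both ratios were larger than the spread between replicates. Of 16 varying members, 14 were lowest in replicate 3, and Csf1 and Cxcl12 were highest there.

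Mesenchymal transcripts were high and markers of differentiated neural cells mostly low. Of 18 mesenchymal glioma genes, 17 were detected, at the 100th percentile, led by Vim, Fn1 (2611 ± 444), Anxa2 (1597 ± 175) and Anxa1 (927 ± 51.7), and Chi3l1 had 1 count in all. Of 18 proneural glioma genes, 9 were detected, at percentile 8.07, led by Tcf4 (383 ± 104), Tcf12 (280.4 ± 36.2), Ncam1 (212 ± 17.9) and Sox2 (113 ± 2.85). The mesenchymal median exceeded the proneural median by 5.23 ± 0.07 on the log2 scale, larger than the spread between replicates. Cd44 (870.1 ± 75.05) lay 2103-fold above Prom1 (0.443 ± 0.178), which was under 1 CPM in every library. Of 16 neural stem and progenitor genes, 11 were detected, at the 81.9th percentile, led by Nes (427 ± 20.2), Itga6 (213 ± 1.91), Id3 (194 ± 27.2) and Id1 (132 ± 44.7), while Fabp7, L1cam, Msi1, Pax6 and Prom1 lay below 1 CPM. Of 16 matrix and invasion genes, 15 were detected, at the 100th percentile, with Spp1, Sparc (2856 ± 592), Fn1 and Itgb1 (2414 ± 369) highest and Mmp9 below 1 CPM.

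Of 14 astrocyte markers, 7 were detected, led by the gap junction gene Gja1 (479 ± 56.4), Glul (56.0 ± 6.997), Sox9 (27.3 ± 5.88) and Slc4a4 (16.9 ± 3.41). Gfap, the filament of mature astrocytes, had 0 counts in all 3 libraries, which allows up to 0.103 CPM in the shallowest one. Against a floor of 3 counts over the 3 libraries, Vim was at least 156610-fold and Nes at least 9147-fold higher than Gfap per base of union exon length, and with the longest transcript Nes was at least 6014-fold higher. Of 14 oligodendrocyte progenitor markers, 4 were detected: Vcan (313 ± 25.8), Pdgfra, Cspg4 (46.9 ± 2.10) and Nkx2-2 (5.14 ± 1.40). Olig2, a lineage factor, had 0 counts, so that Sox9 was at least 546-fold higher per base over the same floor. Of 12 myelin markers, 2 were detected, Aspa (51.0 ± 2.69) and Cnp (19.2 ± 3.62), and 1, Mal, was split. Of 16 neuron markers, 4 were detected: Tubb3 (19.7 ± 2.16), Gad2 (16.5 ± 5.87), Eno2 (9.25 ± 3.53) and Map2 (4.18 ± 1.31). The astrocyte median exceeded the neuron median by 1.03 ± 0.17 and the progenitor median lay below the astrocyte median, at −1.26 ± 0.26, on the log2 scale. Both differences exceeded the spread, and with a pseudocount of 0.1 they were 2.02 and −3.34. The progenitor median itself lay near 0 (0.0348 CPM), so the size of the second difference depends on the pseudocount. Progenitor and myelin markers did not differ by more than the spread with all 3 libraries (−0.04 ± 0.05, exact two-sided p = 0.5). The sign turned without gene length (0.01) and with list means (0.33). With list means the difference was larger than the spread, and so was a negative difference without replicate 2. The myelin median lay near 0 too (0.0199 CPM), so the difference of these medians does not compare the detected members.

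**Figure D2:**
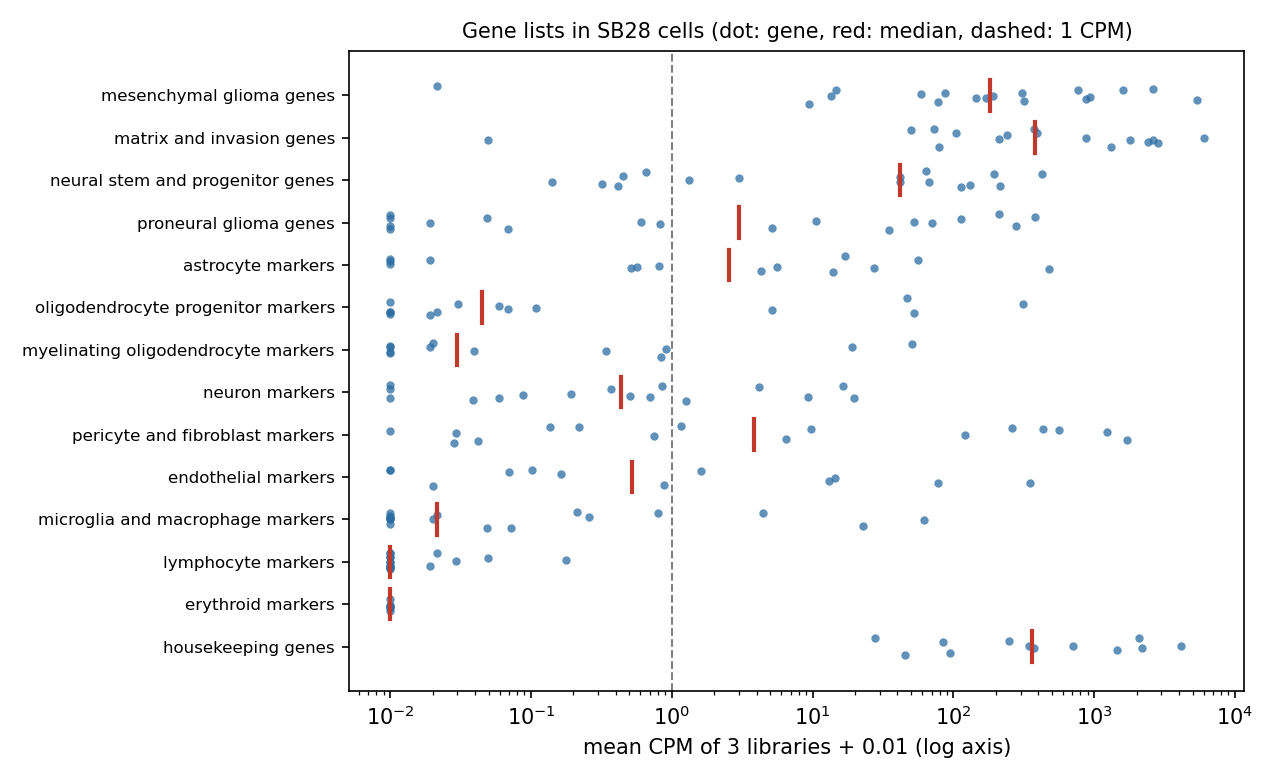
Mean CPM over 3 libraries + 0.01 (log axis) of the members of 14 gene lists, with 1 dot per gene, the list median in red and a dashed line at 1 CPM. Mesenchymal and matrix medians lie at 182 and 383 CPM, and the medians of lymphocyte and erythroid markers lie at 0.

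None of 16 lymphocyte markers and none of 6 erythroid markers was detected, and 11 and 6 of them had 0 counts in all libraries. The lymphocyte marker with the highest value, Lck, reached 0.166 ± 0.182 CPM. Of 17 microglia and macrophage markers, 3 were detected, among them Tmem119 (75.6, 69.7 and 41.2) and Cd68 (4.43 ± 0.964), and 7 had 0 counts. Of 12 endothelial markers, 5 were detected, led by the cadherin Cdh5 (351 ± 42.2), Flt1 (95.8, 98.4 and 39.8), Esam (14.4 ± 5.44) and Egfl7 (13.2 ± 0.689). Of 16 pericyte and fibroblast markers, 8 were detected, led by the collagens Col1a1 (2045, 1957 and 1149), Col1a2 (1497, 1482 and 717), the actin Acta2 (561 ± 45.6) and Col3a1 (562, 545 and 187). The pericyte and fibroblast median exceeded the endothelial median by 1.45 ± 0.47 and the astrocyte median exceeded the microglia median by 1.26 ± 0.29, both larger than the spread. With a pseudocount of 0.1 they were 2.67 and 3.37. The microglia median itself lay near 0 (0.0115 CPM), so the size of the second difference depends on the pseudocount. The pericyte and fibroblast median exceeded the astrocyte median by 0.51 ± 0.23, and this call was lost without replicate 1 (0.43), without replicate 2 (0.46), with replicates 1 and 2 averaged (0.42) and with a pseudocount of 0.1 (0.88). With list means the difference was 1.45. All 8 detected pericyte and fibroblast markers varied between libraries, and 7 were lowest in replicate 3. Of the 32 lists, 9 lay in the top 2.5% of random lists and 10 in the bottom 2.5%. The second count was 1 with genes at 0 counts in the background. It was 0 with detected genes and members only, a setting that drops the low members themselves.

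Of 16 glioma antigens, 10 were detected, at the 47.5th percentile, led by Epha2 (159.8 ± 14.98), Gpnmb (154 ± 12.1), Sox2 and Birc5 (64.5 ± 24.3). All 16 hypoxia and glycolysis genes were detected, at the 99.9th percentile, led by Pkm, Pgk1 (1264 ± 49.8), Ldha (945 ± 90.6) and Hk1 (239 ± 3.29). All 14 stress and immediate early genes were detected, at the 100th percentile, led by Egr1, Jun (359.8 ± 7.19), Atf4 (281 ± 12.04) and Fos (89.2, 94.1 and 188). All 12 housekeeping genes were detected, at the 100th percentile, led by Actb, Rplp0 (2183 ± 110), Gapdh (2079 ± 77.1) and Ppia (1452 ± 67.5). Of the sex chromosome genes, Xist was detected (91.9, 104 and 248), and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had 0 counts in all 3 libraries. Xist lies on chromosome X at 103460366 to 103483254.

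Replicate 3 differed from replicates 1 and 2 in many genes. The chi-square per degree of freedom was 2.18 between replicates 1 and 2, 74.5 between 1 and 3, and 65.9 between 2 and 3, where counting noise alone gives 1. Of 12737 genes compared, 100 (0.785%), 884 (6.94%) and 900 (7.07%) lay at least 2-fold apart in these pairs. The chi-square test called 8381 genes (65.8%) as varying between the 3 libraries. Of these, 4075 were lowest and 4156 highest in replicate 3. At least 2-fold apart were 960 genes, of which 654 were lowest and 289 highest in replicate 3. Without replicate 3, 241 genes were called, which separate preparations of one RNA could also give. Replicates 1 and 2 were counted as separate samples because the labels list them so. The edgeR common dispersion was 0.0294, a biological coefficient of variation of 17.1%, and 0.000422 (2.05%) without replicate 3, 0.0465 without replicate 1 and 0.0480 without replicate 2. Reads outside annotated genes made up 5.19%, 5.27% and 6.54% of all records in replicates 1, 2 and 3.

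Among the 15 varying genes with the largest ratio between libraries at a mean of at least 10 CPM, 12 were lowest in replicate 3 and 3 were highest there. The imprinted RNA H19 (37.6, 34.2 and 2.70), the astrocyte aldolase Aldoc (20.2, 20.4 and 1.65), the enkephalin precursor Penk (218, 215 and 20.04) and Ace (186, 185 and 27.2) were lowest in replicate 3 by 13.9-, 12.3-, 10.9- and 6.81-fold. Txnip, Cadps, Nrep, Trp53inp1, Ccl5, Apod, 9930111J21Rik1 and Klhl24 followed, with ratios of 4.20 to 5.88. The dehydrogenase Aldh3a1 (16.3, 16.04 and 87.5), the quinone reductase Nqo1 (39.0, 41.6 and 199.5) and Elmod1 (8.27, 8.45 and 38.7) were highest in replicate 3.

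Whole gene lists differed in the same way. Of 27 lists with enough detected members, 15 had a range of shifts in the top 2.5% of matched random lists. If the lists were drawn at random, 0.675 would be there. Many lists share members, so these 15 are not independent of each other. Without replicate 3, 1 list had a range in that top 2.5%. The median over all detected genes shifted by 0.00 in each library. Interferon-stimulated genes shifted by 0.31, 0.36 and −1.19 on the log2 scale in replicates 1, 2 and 3, and by −0.78 in replicate 3 among members at 5 CPM or more. Neuron markers stood at −0.69 in replicate 3, pericyte and fibroblast markers at −0.58, checkpoint ligands at −0.39, cell cycle inhibitors at −0.38, interferon signalling genes at −0.35, cytokines at −0.33, proneural genes at −0.31, matrix genes at −0.28, astrocyte markers at −0.27, MHC class I genes at −0.24, hypoxia genes at −0.21, p53 genes at −0.18 and mesenchymal genes at −0.15. Cell cycle genes lay the other way (−0.19, −0.17 and 0.31), with 25 of 26 varying and 23 of those highest in replicate 3. Of the other 12 lists, PDGF genes (−0.22, 97.4th percentile) and microglia markers (−0.40, 97.0th) lay just under the limit. RAS-MAPK genes (0.01), oligodendrocyte progenitor markers (0.02), housekeeping genes (0.04), mismatch repair genes (0.06), stem and progenitor genes (0.08), glioma antigens (0.08), MAPK output genes (−0.08), endothelial markers (−0.07), stress genes (−0.07) and receptor tyrosine kinases (−0.12) lay within the range of random lists.

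**Figure D3:**
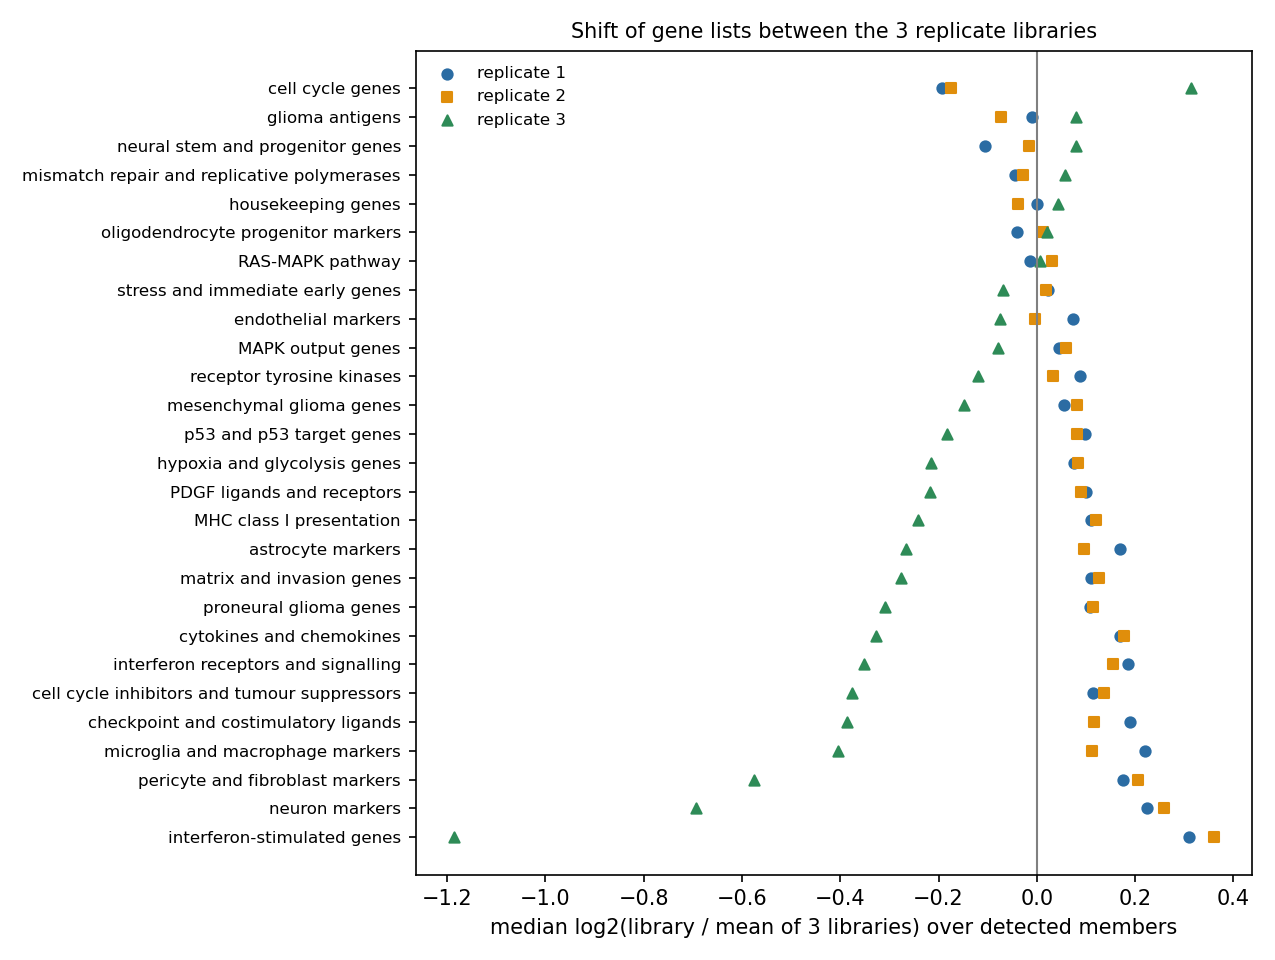
Median log2(library / mean of 3 libraries) over the detected members of 27 gene lists, 1 marker per replicate library, with 0 for no shift. Replicates 1 and 2 lie close together, while replicate 3 lies at −1.19 for interferon-stimulated genes and at 0.31 for cell cycle genes.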

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

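The tests of fibroblast, endothelial and microglial RNA below were chosen after the results they bear on were seen, as were the genes named in them. The comparisons leave out part of the reads. Reads aligned to more than 1 place made up 9.12% of all records on average over the 3 libraries, reads outside annotated genes 5.66% and reads overlapping more than 1 gene 1.03%. With 3 samples in the group, a single far sample was not tested for.

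Replicate 3 lay apart from replicates 1 and 2. The totals argue against unequal depth as the cause, since replicate 3 (32632858 counts) lay between replicate 2 (28990128) and replicate 1 (36019009). After thinning to the smallest total, the chi-square per degree of freedom of replicates 2 and 3 stayed at 62.3, against 2.06 for replicates 1 and 2. Thinning leaves the expected share of each gene unchanged, so this outcome was nearly fixed in advance and excludes nothing. GC content and gene length accounted for 0.860% of the variance of the log2 ratio of replicate 3, which excludes them as the main cause. Dcn and Lum together reached at most 0.550% of the Col3a1 excess of replicates 1 and 2. Both genes were picked after their low values had been seen, so this cannot exclude fibroblast RNA in those replicates. Dcn (1.30, 1.90 and 0.276) was lowest in replicate 3, as Col3a1 was. A sparser culture of replicate 3 stays open, because YAP target genes went both ways (median shift 0.0426, 75.5th percentile). A shared source of replicates 1 and 2, such as one culture or RNA, may also separate them and stays open because the labels do not describe it, and the design names no biological difference between the replicates.

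Some markers of endothelial cells and microglia were detected where 6 of the 12 endothelial and 13 of the 17 microglia markers lay below 1 CPM in all libraries. The median of the 11 other endothelial markers was at most 0.0607% of Cdh5 in any library. Because 6 of these 11 were already known to lie below 1 CPM, a low median was fixed in advance. It therefore cannot exclude RNA from endothelial cells. Pecam1 stood at 0.0600 CPM, and Tie1 and Cldn5 had 0 counts. Cdh5 was not alone: Flt1 (95.8, 98.4 and 39.8 CPM in replicates 1, 2 and 3), Esam (14.4 ± 5.44) and Egfl7 (13.2 ± 0.689) were detected too, and Pecam1, Tie1 and Cldn5 lay far below these as well. The test for RNA from microglia or macrophages has the same limit. The 16 other markers had a median of at most 0.0372% of Tmem119, but 13 of them were already known to lie below 1 CPM. C1qa and Tyrobp had 0 counts, while Cd68 (4.43 ± 0.964 CPM) was among the markers detected. Cdh5 lies on chromosome 8 at 104101625 to 104144511. No biological explanation was tested.

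Xist was higher in replicate 3 (248 CPM) than in replicates 1 and 2 (91.9 and 104). A shift of all X-linked transcripts was excluded, since the median shift of 391 other detected X-linked genes was −0.00243 against 0.746 for Xist. A larger share of cells with an inactive X may account for it and stays open, because genes that escape inactivation had a median shift of 0.0766 (73.8th percentile), with 3 of 5 varying.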

How the results depend on the processing

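Averaging replicates 1 and 2, the background with genes at 0 counts, and DESeq2 size factors and left-out replicates for list shifts were chosen after the data were examined. No paired analysis was possible because the samples form 1 group. Totals without mitochondrial genes were not run, since the files list 0 such genes. Genes detected ranged from 9837 to 14401 over the alternatives and detected list members from 281 to 334; gene pairs larger than their spread were 17 or 18 and list pairs 7 to 9. At 5 CPM, detected members changed to 0 for MHC class II, 7 for interferon-stimulated genes, 10 for cytokines and 4 for astrocyte markers; the stricter limit itself removes low members. Of 10 lists at or below the 2.5th percentile, 1 lay there with a background that includes genes at 0 counts, so low percentiles depend on the background. With detected genes and members only, 0 lay there. That setting drops the undetected members that made these lists low, and it leaves out lists with too few detected members. Its 0 was therefore nearly fixed in advance and says nothing about the background. Over the settings, 9 to 13 lists lay in the top 2.5%. Leaving out 1 replicate gave 241 to 8206 varying genes, an edgeR dispersion of 0.000422 to 0.0480, and 1 to 15 shifted lists. In each the low end came without replicate 3, which shows that this library sets them. The DESeq2 median dispersion was 0.00836; the cause of its distance from the edgeR value was not tested. Moves of more than 1 SD were counted for each pair or list under each alternative setting. There were 24 for gene pair ratios (102 did not move), 18 for list pair differences (45 did not) and 77 for list percentiles (110 did not). Of the called values, 0 changed sign. Genes under about 0.1 CPM rest on 3 counts or fewer per library, so depth limits statements about them.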

Other observations

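The genes in this part were chosen after their values were seen, as was the wider list of lipid genes after Scd2 had been seen to be lower in replicate 3; the test of that list was set before its values were seen. Transcripts of the homeobox cluster genes were almost undetected. Of 39 Hox genes, 0 were detected in all 3 libraries and 38 had 0 counts in all. The forebrain factor Emx2 stood at 5.74 ± 0.642 CPM (SD, n = 3). Otx2 had 0 counts. Regulators of mesenchymal state were detected beside them: Prrx1 (471 ± 66.3), Zeb1 (94.8 ± 9.02), Zeb2 (65.0 ± 4.59), Twist2 (59.3 ± 2.96), Twist1 (38.3 ± 3.83), Snai1 (34.6 ± 3.001) and Snai2 (32.9 ± 0.719). The neural crest and muscle factor Pax3 stood at 27.5 ± 0.531.

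Besides Nqo1, the redox genes Srxn1 (67.5, 67.0 and 124), Txnrd1 (258, 252 and 414), Gclc (44.9, 42.5 and 76.0), Gclm (63.0, 61.1 and 93.2) and Slc7a11 (46.5, 45.6 and 74.8) were highest in replicate 3. Hmox1 (97.8, 96.9 and 88.4), another target of the same pathway, and its regulator Nfe2l2 (234, 232 and 207) were lowest there. Cyp1b1 (20.2, 20.9 and 71.3) and Tiparp (174, 182 and 228), targets of the aryl hydrocarbon receptor, were highest in replicate 3, as was Aldh3a1, while Ahr itself (102, 101 and 93.9) was lowest there.

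Sterol and fatty acid synthesis genes shifted with Scd2. All 23 genes of the list were detected and varied, and all 23 were lowest in replicate 3, for example Fdps (538, 533 and 206), Lss (239, 237 and 97.3) and Mvd (121, 119 and 42.7). Their median shift of −0.622 lay below all matched random lists, at percentile 0, in a test that could have come out at or above 0. A shared change of lipid synthesis in the replicate 3 library is therefore a hypothesis that fits these values and may reflect culture conditions, which the labels do not give.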
